A study of Arabidopsis thaliana with 3 samples.

How the data were processed

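Single-cell RNA sequencing was done on lateral root primordium cells of Arabidopsis thaliana, accession Columbia-0. Per the labels' protocols, 5-day-old seedlings expressing a nuclear mCherry reporter under the HB53 promoter were turned into protoplasts, mCherry-positive cells were sorted, and libraries were read as single-end reads of 150 bp. The labels name 1 group of 3 replicates. The authors deposited 1 table of raw read counts for 32833 genes in 573 wells, and its values are whole numbers with totals that differ between wells. The other file the authors deposited is text that ties each well to a raw file, whose name gives flow cell, plate and plate position, and to an archive run. It names no replicate, and which runs belong to which replicate is not given in the sources used here and was not looked up. The genome build was TAIR10, per the submitters' processing notes; the aligner, the counting rule, its strand setting and any read filter are not given in the sources used here. No molecular identifiers are named, so reads copied by PCR are counted more than once, and intervals and floors cover counting error only. Reads shared between close gene copies or overlapping genes cannot be assigned with certainty.

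Because no well could be tied to a replicate from these sources, all wells were treated as 1 sample, as the design fixed before the data were examined has it for this case. The planned edgeR quasi-likelihood test, its alternatives, the list tests and the replicate block were therefore not run, and no p-value was computed. The 3 flow cells, with 2 plates each, were treated as technical batches, and values within each were compared. No source used here says whether they coincide with the 3 replicates. Counting intervals are exact 95% intervals, binomial (Clopper-Pearson) for shares of cells and Poisson for sums of reads. For a gene without a read, a limit of 3 counts is given beside the exact interval. Wells with at least 500 detected genes were kept as cells, with no limit on organelle reads. No doublet caller was run, since each column is 1 plate well, and wells with more than 1 cell cannot be excluded. Pearson correlations of log2 CPM between the sums of pairs of flow cells were 0.918 to 0.923 across genes, and genes are not independent of each other.

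Counts were divided by the cell total, scaled to 10000 and log-transformed. A seeded random 0.5 of the genes outside the fixed lists was used to find 1500 variable genes. The flow cell mean was removed per gene, values were scaled and clipped at 10, and 20 principal components, 15 neighbours and Leiden resolution 0.8 (seed 1) gave the clusters. The tested genes were the members of the fixed lists and the other genes not used for clustering, 16601 in all. A gene was measured with at least 10 reads in at least 5 cells of the comparison, which held for 9802 genes. Reads were summed over the cells of a cluster and over all other cells, and the log2 ratio of CPM was corrected with the trimmed mean of M values (trim 30% of M and 5% of A). The plan had each cluster against the mean of the other clusters; this became an alternative, since without replicates no model was fitted. A sum of 0 reads stands at a floor of 3 reads over the group, in list medians too. Folds given as at least a value use this floor and do not cover variation between cells.

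Cycling classes were formed within each flow cell from the share of reads in the S phase and the G2 and M phase lists, as the upper and the lower 1 in 3 of cells. Here 32782 genes were tested and 17571 measured, without the genes of the score. For each list with at least 3 measured members the median log2 fold was ranked among 10000 random lists matched on mean level in 20 bins. As background for counts of members with the same direction on all 3 flow cells, the same share over all measured genes was computed. Random directions would give 12.5% of genes in 1 given direction on all 3. List shares of cells thinned to 115851 reads, the percentile 20 of totals, were correlated within each flow cell (Spearman).

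The lists were fixed before the data were examined. Tissue lists were pericycle (7 genes), vascular precursor (10), xylem (9), phloem and companion cell (11), endodermis (18), cortex (4), epidermis and root hair (13), root cap (6), quiescent centre and stem cell niche (10) and green tissue (6). Process lists were lateral root initiation and primordium regulators (30), auxin response and transport (37), cytokinin response (16), S phase (23), G2 and M phase (28), D cyclins and kinase inhibitors (13), cell wall remodelling (12), and protoplasting and stress response (15). Ribosomal protein genes (101) were taken by product name, and some of these names are shared with organellar subunits. A narrower name pattern was tried after the first values had been seen. It changed the genes held out of clustering and gave 9 clusters, against 8 with the list not held out; the first pattern and its 7 clusters were kept.

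Named genes were, per comparison, the 8 with the largest higher and the 5 with the largest lower fold. They had to have at least the median level of measured genes, to exceed 2 floors and to move in the same direction on all 3 flow cells. Up to 12 members of the fixed lists, taken by size of fold in place of a p-value, were added. HB53, LBD16, GATA23, PUCHI and CYCB1;1 were meant to be included for every comparison, but the text below does not give them for every cluster. HB53, PUCHI and CYCB1;1 are each given for 1 cluster, and LBD16 and GATA23 for none. For the cycling classes all of them but GATA23, which had no read, are given. The clusters shown for these genes are thus a selection, and a value not given does not mean no difference. The same-direction and level conditions for the untested case were set after it was known that these sources hold no replicate map. A cluster was named after a tissue only where at least 3 of its fixed markers were detected and its leading genes did not go against the name, which left all clusters but 1 with numbers. Gene symbols came from RefSeq's annotation of assembly TAIR10.1, which matched 32548 of 32833 identifiers; no coordinates were taken from it.

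The scaling factor was checked against edgeR 4.0.16 in R 4.3.3, with a difference of 0 in log2. In simulated cycling classes with 200 changed genes, folds of 2 and 4 were planted by thinning the reads of 1 class. After subtracting the fold of the same cells before thinning, median log2 values of 0.99 and 1.99 were recovered. This checks the calculation and not the noise between cells. Without that subtraction, 97% and 100% of the changed genes lay above 0. With class labels shuffled, random lists had a mean percentile of 50.3. They were ranked against other random lists, so this checks the calculation only. The fixed lists were not run with shuffled labels, so how far genes that vary together spread a list's percentile was not examined. With the same shuffled labels, the log2 fold of single measured genes had a standard deviation of 1.43. Single-gene folds of that size therefore arise between random classes of cells. These classes had the size of the cycling classes. Clusters of 13 to 64 cells, where single cells weigh more, were not simulated. Alternatives covered the cell filter, the gene filter, the scaling, the clustering settings, the class score, leaving out each flow cell and other reference groups. Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.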

Results

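The cells came from Columbia-0 roots of Arabidopsis thaliana at 5 days after germination. They carried a nuclear triple mCherry reporter under the promoter of HB53 (AT5G66700), a homeodomain-leucine zipper gene. Protoplasts with mCherry signal were sorted, which the labels equate with lateral root primordium cells of stages I to IV. Each column of the count table is 1 plate well and is taken as 1 cell here. The count table held 573 wells from 6 plates, sequenced on 3 flow cells. A total of 322 wells had at least 500 detected genes and are called cells here, with 102, 96 and 124 on flow cells 1, 2 and 3. A cell had a median of 245742 reads (range 8315 to 1459543) and 4009 detected genes (range 506 to 9516). Median reads per cell were 408532, 440181 and 132330 on the 3 flow cells, while median gene numbers were 3974, 4172 and 3908. The labels name 3 replicates, but no source used here ties a well to a replicate, so all cells count as 1 sample. The values below therefore have no replicate error and no test, and intervals are 95% intervals that cover counting error only. Values within each flow cell stand in their place. Flow cells are treated as technical batches, and whether they coincide with the 3 replicates is not known.

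**Figure D1:**
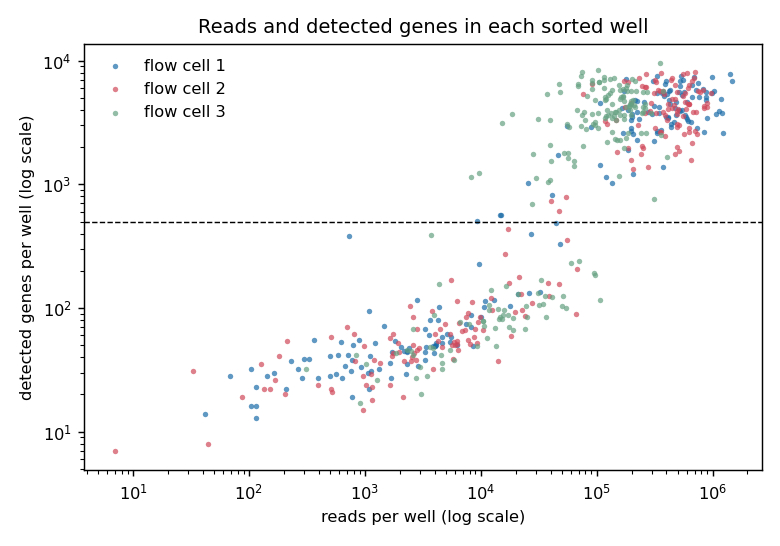
Each point is 1 sorted well, with its reads on the horizontal axis and its detected genes on the vertical axis, both on log scales, coloured by flow cell. The dashed line marks 500 detected genes; 322 wells lie at or above it and 251 below it.

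The first question was how widely known regulators of lateral root formation were detected in the sorted cells. IAA28 (AT5G25890), an auxin response repressor of early founder cell specification, had reads in 58.4% (52.8 to 63.8) of cells, and LRP1 (AT5G12330), a zinc finger gene named after the lateral root primordium, in 55.9% (50.3 to 61.4). The AP2-type regulators PLT3 (AT5G10510) and PLT5 (AT5G57390) were detected in 46.6% and 35.7% of cells. LBD16 (AT2G42430), which acts downstream of auxin in lateral root initiation, was detected in 36.0% (30.8 to 41.5), with 31.4 to 38.5% across flow cells. HB53 itself had reads in 11.5% (8.22 to 15.5) of cells, and 11.3 to 11.8% across flow cells. For PUCHI (AT5G18560), an AP2/ERF gene of primordium patterning, the share was 9.01% (6.11 to 12.7), with 7.84 to 10.5% across flow cells. The mitotic cyclin CYCB1;1 (AT4G37490) was detected in 6.52% (4.08 to 9.80), with 6.25 to 6.86% across flow cells. No read of GATA23 (AT5G26930), a GATA factor of founder cell specification, was counted in any of the 322 cells, which allows a share of up to 0.932% of cells with a read at a limit of 3 counts, and up to 1.14% by the exact interval. LBD29 (AT3G58190) and LBD18 (AT2G45420) were each detected in 0.932% of cells. At least 3 of the 30 regulators on this list were found in 79.5% (74.7 to 83.8) of cells.

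With each cell thinned to 115851 reads, which left out 65 shallower cells and kept 257, HB53 was detected in 10.1%, LBD16 in 36.2%, PUCHI in 7.78% and CYCB1;1 in 7.0% of cells. A share of cells with a read depends on capture as well as expression, so a cell without a read is not shown to lack the transcript.

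**Figure D2:**
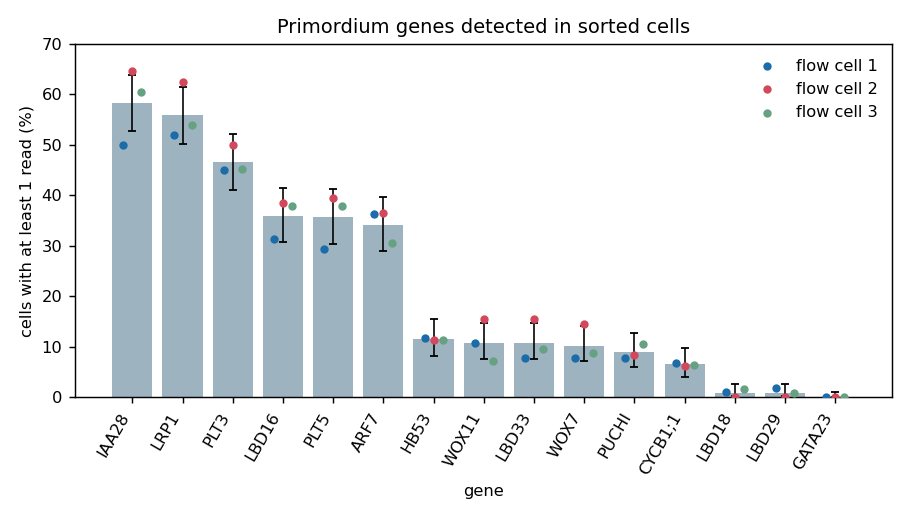
Bars give the share of the 322 cells (%) with at least 1 read of each primordium gene, error bars the exact 95% binomial interval, and points the share within each flow cell. HB53 lies at 11.5% and LBD16 at 36.0%, and GATA23 had no read.

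Markers of other root tissues were counted to ask which of them the sorted cells carried. At least 2 vascular precursor markers were detected in 60.6% (55.0 to 65.9) of cells, led by TMO6 (AT5G60200), a DOF factor of the young vasculature, in 56.5%. The corresponding share was 22.7% (18.2 to 27.6) for phloem and companion cell markers, 18.6% (14.5 to 23.3) for pericycle markers and 13.4% (9.84 to 17.6) for endodermis markers. Markers of the quiescent centre and stem cell niche reached 8.07% (5.34 to 11.6) of cells, with WOX5 (AT3G11260), a homeobox gene of the root stem cell niche, in 12.1% and BBM (AT5G17430), an AP2-type stem cell regulator, in 10.6%. Green tissue markers met the same limit in 10.2% (7.16 to 14.1), epidermis and root hair markers in 2.17% (0.878 to 4.43) and xylem markers in 1.24% (0.339 to 3.15). No cell held 2 or more markers of the cortex or of the root cap, with an exact upper end of 1.14% of cells. This limit could hardly be met, since only 2 of 4 cortex and 1 of 6 root cap markers were detected in at least 5 cells. At least 1 marker was found in 11.8% of cells for the cortex and in 4.04% for the root cap. The upper end thus does not bound the share of cells of these tissues. Lists differ in length and in how abundant their members are, so these shares do not rank the tissues.

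Hormone, cell cycle and stress genes were counted in the same way. At least 2 auxin response and transport genes were found in 98.4% of cells, with IAA2 (AT3G23030), an auxin-induced repressor, in 91.9%, and at least 2 cytokinin response genes in 44.4%. The same limit was met by S phase genes in 60.2%, by G2 and M phase genes in 32.9%, by D-type cyclins and cyclin-dependent kinase inhibitors in 42.5%, by cell wall remodelling genes in 88.8% and by ribosomal protein genes in 98.1% of cells. Genes of the protoplasting and stress response list were present in 96.6%, among them the zinc finger gene ZAT12 (AT5G59820) in 92.5% and the jasmonate repressor JAZ1 (AT1G19180) in 93.2% of cells.

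The next question was whether the primordium cells fell into groups with different programmes. Clustering on a random 0.5 of the genes outside the fixed lists gave 7 clusters of 64, 62, 51, 51, 43, 38 and 13 cells, and each was present on all 3 flow cells and all 6 plates. In percentage points, the share of cells in 1 cluster differed most between flow cells for cluster 5, from 11.5 to 14.7%. The small cluster 7 ranged from 2.94 to 5.21%. Among genes detected in at least 30% of a cluster's cells, those with the highest folds included heat shock genes such as Hsp70b (AT1G16030) and HSP17.6II (AT5G12020) in cluster 1, WRKY8 (AT5G46350), NUDT10 (AT4G25434) and ZPR1 (AT2G45450) in cluster 2, chloroplast-encoded genes such as ATCG00590 and ATCG00440 in cluster 3 and PBP1 (AT3G16420) and XTH24 (AT4G30270) in cluster 4. They included DR4 (AT1G73330) and SIAR1 (AT1G44800) in cluster 5, AT3G62630, HDT4 (AT2G27840) and BBM in cluster 6 and ENODL14 (AT2G25060), CYCB2;4 (AT1G76310) and CDC20.1 (AT4G33270) in cluster 7. Some of these helped to build the clusters, whereas the single genes and fixed lists with values for clusters below were kept out of the clustering. The largest genes below had the same direction on all 3 flow cells. Random directions would place 12.5% of genes higher on all 3. In clusters 1 to 5 and 7 the share was 7.55 to 11.5% of measured genes. This condition alone therefore does not set single higher genes apart. Each cluster was compared with all other cells pooled, and the median log2 fold of all measured genes lay between -0.64 (cluster 7) and -0.15 (cluster 1). The percentiles given for lists are ranks among 10000 random lists matched on mean level, and take account of this shift. They take no account of list members that vary together between cells, so an extreme percentile is not a test. Folds given as at least a value, here and for the cycling classes, set 0 reads at the floor of 3 reads. They cover the counting of reads only. Reads of a gene often came from few cells, so they are not lower bounds on the difference between cells. Cluster 7 weighs on the pooled reference for division genes, with 2699 against 7 reads elsewhere for ENODL14 (most of them from 1 cell), 5497 against 285 for CDC20.1, 3403 against 256 for KNOLLE (AT1G08560) and 10360 against 272 for AT5G16250, so low values of these genes in clusters 1 to 6 are in large part set by that cluster. The G2 and M phase median was below 0 in each of clusters 1 to 6. With cluster 7 left out of the reference, an alternative chosen after seeing the data, it was 0.17, -1.34, -3.02, -0.60, -1.43 and -0.0069 in clusters 1 to 6.

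The assignment of cells to clusters was only partly stable. With 20 other random gene subsets the number of clusters ranged from 7 to 10, and the overlap of a cluster with its best match (shared cells divided by cells in either) had medians of 0.396 for cluster 4 to 0.604 for cluster 6. In data with the values of each gene shuffled among cells, 7 clusters were also found, but their best overlap between subsets had a median of 0.123. Such shuffling also largely removes differences between cells in gene number and organelle share. The contrast therefore cannot tell expression programmes from differences in capture. Best matches were at times shared: clusters 1 and 7 each had a match in common with another cluster in 7 of the 20 subsets. With no filter on cells, clusters 1 and 2 had 1 match in common, and so had clusters 4, 6 and 7, so values of these clusters in that setting are those of merged clusters.

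**Figure D3:**
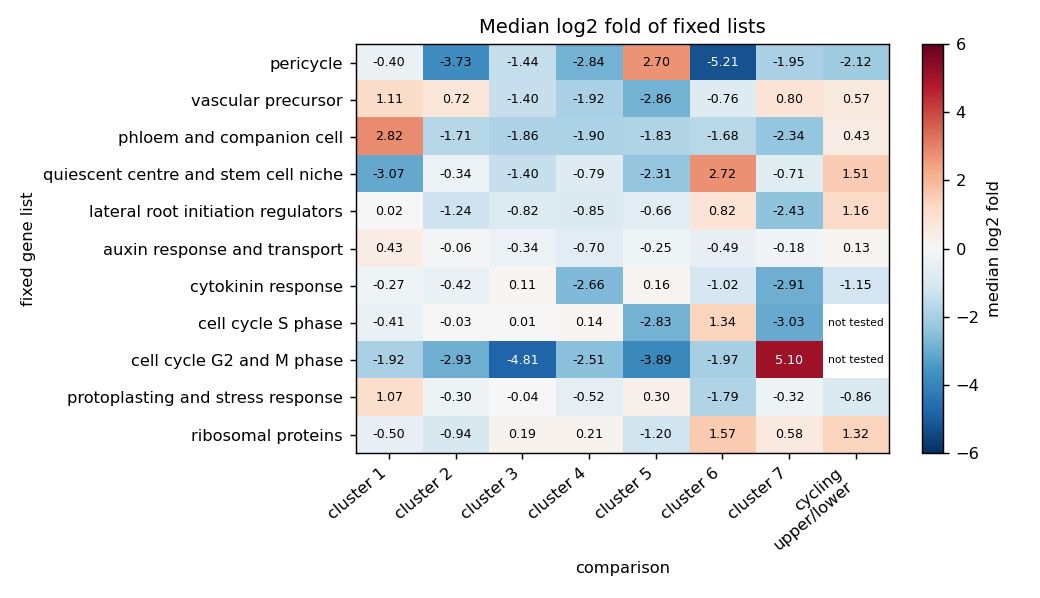
Each cell of the map gives the median log2 fold of a fixed gene list, for each cluster against all other cells and for the upper against the lower cycling class. Red is higher and blue lower; the G2 and M phase list stood at 5.10 in cluster 7 and the pericycle list at 2.70 in cluster 5.

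Cluster 1 (64 cells) had higher levels of phloem and vascular precursor genes. Heat shock and chaperone genes led its ranking, but several of them were used to build the clusters and their levels differed widely between its cells. Among the fixed lists, phloem and companion cell genes had a median log2 fold of 2.82 (percentile 100), with 5 of 8 measured members higher in all 3 flow cells, and vascular precursor genes a median of 1.11 (percentile 100) with 5 of 10 higher. The early phloem DOF factors PEAR1 (AT2G37590) and PEAR2 (AT5G02460) stood at 4.93 and 3.16, the phloem regulators BRX (AT1G31880) and SMXL5 (AT5G57130) at 4.71 and 3.1, and the class III homeodomain gene HB15 (AT1G52150) at 2.51. NAC020 (AT1G54330), a NAC transcription factor, was detected in 39.1% against 8.91% of cells (log2 3.43). Protoplasting and stress response genes were also higher, with a median of 1.07 (percentile 100) and 9 of 15 members higher in all 3 flow cells, including BAP1 (AT3G61190) at 2.49. G2 and M phase genes had a median of -1.92 (11 of 28 lower, percentile 0), against 0.17 without cluster 7 in the reference, and ribosomal protein genes -0.50 (52 of 88 lower, percentile 0). WOX5 had no read in the cluster, at least 229.6-fold lower than elsewhere by reads, and the mitotic activator CDC20.1 was at least 502-fold lower by reads. The auxin-conjugating enzyme gene GH3.1 (AT2G14960) and CRF2 (AT4G23750) stood at -4.01 and -3.27.

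The other largest differences in cluster 1 were CER1 (AT1G02205) at 5.30, a wax alkane synthesis gene, AT1G07710 at 4.49, AT5G56050 at 4.48, PIP5K4 (AT3G56960) at 4.28 and AT1G26650 at 3.41. A single cell gave 66.2% of the cluster's CER1 reads and 77.0% of its PIP5K4 reads. Lower genes included GSTF7 (AT1G02920) and AT2G15780 with no read, LTP3 (AT5G59320) with 4 against 4041 reads and ENODL14 with 3 against 2703, nearly all of these in cluster 7. Of all measured genes, 11.5% were higher and 20.6% lower in all 3 flow cells. Best overlap over the other gene subsets was 0.402 (0.272 to 0.609), and the phloem median was above 0 in 18 of 20 subsets. It was -0.51 when flow cell means were not removed. With 3000 variable genes the stress median was -0.54 and the vascular precursor median -0.0076. The vascular precursor median was 0.37 without the first flow cell and 1.74 without the second, the phloem median 2.11 without the third flow cell, and the G2 and M phase median -2.96 without the third flow cell and 0.0020 against the mean of the other clusters. With another gene subset BRX stood at -0.37 and PEAR2 at -1.74, and without removal of flow cell means NAC020 at -0.37 and SMXL5 at -0.96.

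Cluster 2 (62 cells) had low levels of ribosome genes and, by a smaller margin without cluster 7 in the reference, of G2 and M phase genes. S phase genes as a list stood at -0.034 (percentile 66.2), and at -1.17 and 0.058 without the first and the third flow cell. The median log2 fold was -2.93 for G2 and M phase genes (19 of 28 lower in all 3 flow cells, percentile 0), -0.94 for ribosomal protein genes (72 of 88 lower, percentile 0), -3.73 for pericycle genes (4 of 6 lower, percentile 0.110) and -1.24 for lateral root initiation regulators (10 of 26 lower, percentile 0.140). Flow cell medians were -2.80 to -0.79 for pericycle genes, all short of the pooled value, and -2.59 to -0.23 for initiation regulators. NPF7.3 (AT1G32450), which loads nitrate into the xylem, had no read there and was at least 542-fold lower, whereas within the same list SKOR (AT3G02850) stood at 1.28, higher in all 3 flow cells, and PHO1 (AT3G23430) at 0.24. The B-type cyclins CYCB1;4 (AT2G26760) and CYCB2;4 and the nodulin-like genes ENODL14 and ENODL15 (AT4G31840) also had no read, at least 219.8, 179, 215 and 365-fold lower by reads. WOX5 was at least 210.4-fold lower, and the mitotic kinase AUR2 (AT2G25880), CDC20.1 and RBCS1A (AT1G67090) stood at -3.14, -5.29 and -3.92. RBCS1A changed sign, to 5.27 with another gene subset and 0.69 against the mean of the other clusters. Within the initiation list, members also went the other way: IAA28 was detected in 85.5% against 51.9% of cells (log2 1.73), and WOX11 (AT3G03660) and ARF5 (AT1G19850) stood at 2.79 and 1.57; these 3 and SKOR and PHO1 were chosen after their values were seen.

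Higher genes in cluster 2 were the chitinase EP3 (AT3G54420) at 4.01 (43.5% against 7.69% of cells), the transcription factor MYB41 (AT4G28110) at 3.87 (25.8% against 6.54% of cells), the cupredoxin gene AT2G15780 at 6.55, AT5G52390 at 6.22, AT2G26690 at 4.76, PS2 (AT2G29900) at 4.73, AT1G19540 at 4.02 and SYP41 (AT5G26980) at 3.81. Lower genes were PBP1 with 2 against 14760 reads, MYB68 (AT5G65790) with 1 against 4618, the peroxidase gene AT4G33420 with 1 against 4272, LTP3 with 1 against 4044, LBD33 (AT5G06080) with 1 against 2191, the cytokinesis syntaxin KNOLLE with 3 against 3656 and AT5G16250 with none. Of all measured genes, 26.5% were lower and 11.1% higher in all 3 flow cells. The overlap over other gene subsets was 0.562 (0.373 to 0.731), and both the G2 and M phase median (-4.33 to -2.07) and the ribosomal median (-1.24 to -0.55) stayed below 0 in all 20 subsets. The G2 and M phase median was -4.66 and -4.67 without the first and the third flow cell. The pericycle median was -2.79 and -2.92 without the second and the third flow cell and -1.81 against the mean of the other clusters.

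Cluster 3 (51 cells) had fewer detected genes and a higher organelle share at the median, while single cells reached 4247 genes. Its median gene number was 1967, against 4456 in the other cells, and its median organelle share 8.38%, against medians of 1.81 to 2.78% in the other clusters. Green tissue genes had a median log2 fold of 3.39 (percentile 100), with RBCS1A, the small subunit of Rubisco, at 6.47 and CAB1 (AT1G29930), a chlorophyll-binding protein gene, at 4.26. These values came mostly from 1 cell, which gave 83.0% of the RBCS1A reads and 85.5% of the CAB1 reads of the cluster. The same held for the largest higher genes, AT2G16730, AT4G25090, AT2G47670, CA1 (AT3G01500), AT2G28990, AT2G40050, AT5G38310 and PnsL1 (AT2G39470) (log2 7.32 to 10.58), where 1 cell gave 67.6 to 99.2% of the reads. G2 and M phase genes stood at -4.81 (22 of 28 lower in all 3 flow cells, percentile 0). The auxin receptor gene TIR1 (AT3G62980) was detected in 13.7% against 50.9% of cells (log2 -2.92), IAA10 (AT1G04100) in 5.88% against 32.8% of cells (-3.77), and WOX11, WOX5 and HB15 stood at -4.10, -3.75 and -3.33. LCB1 (AT4G36480), DGD1 (AT3G11670), NHL8 (AT1G32340) and CSN5A (AT1G22920) had 1 read each in the cluster, against 3759 to 5848 elsewhere, KNOLLE had 2 against 3657, ENODL14 3 against 2703 and AUR1 (AT4G32830) 3 against 2581, and AT5G16250, ENODL15 and CYCB1;4 had none.

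In cluster 3 the median of all measured genes was -0.48, and 26.4% of them were lower in all 3 flow cells. The green tissue median was -0.73 with another gene subset, -0.94 at resolution 1.2, -2.68 with no filter on cells and 0.60 and 4.91 without the first and the second flow cell. The G2 and M phase median was -3.18 without the second, and overlap over other gene subsets was 0.479 (0.264 to 0.661).

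Cluster 4 (51 cells) had low medians for several lists, and more detected genes than the other cells (median 5598 against 3850), which can raise the shares of cells with a read. Vascular precursor genes had a median log2 fold of -1.92 (percentile 0), with 7 of 10 lower in all 3 flow cells. The class III homeodomain genes PHV (AT1G30490) and HB15 stood at -6.02 and -4.66, and PHV was detected in 3.92% against 24.7% of cells. Cytokinin response genes had a median of -2.66 (6 of 14 lower, percentile 0.0200), including the response regulator ARR5 (AT3G48100) at -3.23. Pericycle genes stood at -2.84 (percentile 0.220), phloem and companion cell genes at -1.90 (percentile 0.610) and green tissue genes at -3.27 (percentile 0.180). G2 and M phase genes stood at -2.51 (16 of 28 lower, percentile 0), although CYCB1;1 was detected in 15.7% against 4.80% of cells (log2 2.28), with 1 cell giving 54% of its reads. A cell held a mean of 1.80 detected G2 and M phase genes in the cluster and 1.80 elsewhere. The heat stress factor HSFA2 (AT2G26150) stood at -4.91, CDC20.1 at -4.75, KNOLLE at -4.05 and ENODL15 at -7.92. The photosynthesis genes GAPA (AT3G26650) and PSBO1 (AT5G66570) stood at -3.27 and -2.79, while RBCS1A and the xylem gene ACL5 (AT5G19530) had no read, at least 427-fold and 181-fold lower.

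Higher genes in cluster 4 were PBP1, a jacalin-like lectin gene, at 3.67 (33.3% against 8.12% of cells), the endoplasmic reticulum body gene NAI2 (AT3G15950) at 2.97, the peroxidase genes AT2G18150 at 3.55 and AT2G38380 at 2.95, the transporter gene AT5G65380 at 3.56, SMC6A (AT5G07660) at 3.12, AT1G66620 at 2.88 and the pyrimidine synthesis gene PYR4 (AT4G22930) at 2.86 (51.0% against 17.0% of cells). ENODL14 had 1 against 2705 reads, DR4 2 against 4302, AT5G16250 4 against 10628 and AT1G11925 5 against 7443. Of all measured genes, 9.73% were higher and 20.06% lower in all 3 flow cells. The overlap over other gene subsets was 0.396 (0.286 to 0.661), and the vascular precursor median stayed below 0 in all 20 subsets (-5.04 to -0.93) and was -3.63 without the first flow cell. NAI2 and AT2G18150 stood at -0.032 and -0.27 among cells with at least 1000 genes. Leaving out 1 flow cell gave -1.83 (first) for the cytokinin median, -1.66 (first) and -3.67 (second) for the pericycle median, -2.66 (first) and -2.62 (second) for the phloem median and -3.32 (the third) for the G2 and M phase median. The G2 and M phase median was -0.59 against the mean of the other clusters.

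Cluster 5 (43 cells) was pericycle-like and low in division genes. Pericycle genes had a median log2 fold of 2.70 (percentile 100), with 4 of 6 measured members higher in all 3 flow cells and flow cell medians of 2.66 to 4.46. PHO1, which exports phosphate to the xylem, was detected in 81.4% against 29.4% of cells (log2 2.88), NPF7.3 in 37.2% against 6.09% of cells (4.29), the potassium channel gene SKOR in 20.9% against 8.96% of cells (2.31) and the glycine-rich protein gene AT4G30450 in 20.9% against 2.15% of cells (7.77). S phase genes had a median of -2.83 (19 of 23 lower, percentile 0), G2 and M phase genes -3.89 (18 of 28 lower, percentile 0) and ribosomal protein genes -1.20 (61 of 88 lower, percentile 0). The replication helicase gene MCM6 (AT5G44635), the histone gene HTR9 (AT5G10400), CDC20.1 and AUR2 stood at -6.31, -5.82, -6.20 and -5.51, and the S phase cyclin CYCA3;2 (AT1G47210) had 2 against 2983 reads. Vascular precursor genes stood at -2.86 (7 of 10 lower, percentile 0.010). PHO1, NPF7.3 and SKOR were named after their values were seen.

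Further genes higher in cluster 5 were the amino acid transporter gene SIAR1 at 5.96 (48.8% against 3.23% of cells), DR4 at 7.18 (41.9% against 2.15% of cells), MSRB5 (AT4G04830) at 5.16 (51.2% against 3.23% of cells), AT2G05510 at 6.82, MYB48 (AT3G46130) at 6.72, AGP14 (AT5G56540) at 6.93 and IGMT1 (AT1G21100) at 5.25. A single cell gave 79.9% of the AT4G30450 reads and 73.2% of the AGP14 reads. WOX11 stood at -5.01, ACR8 (AT1G12420) had 2 against 5628 reads and AUR1 1 against 2583. AT5G16250, AT3G51720, NAC020, ENODL14, ENODL15, CYCB1;4 and ACL5 had no read, at least 132 to 543-fold lower. Of all measured genes, 10.9% were higher and 24.3% lower in all 3 flow cells. The overlap over other gene subsets was 0.525 (0.324 to 0.750), and the pericycle median (1.69 to 3.51) stayed above 0 and the S phase median (-3.81 to -0.42) below 0 in all 20 subsets. Without the first flow cell the vascular precursor median was -4.27 and the pericycle median 3.44, and without the second the G2 and M phase median was -3.24.

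Cluster 6 (38 cells) carried genes of the root stem cell niche, of DNA replication and of the ribosome. WOX5 was detected in 57.9% against 5.99% of cells (log2 4.04) and BBM in 57.9% against 4.23% of cells (4.2). The homeobox gene WOX7 (AT5G05770) was detected in 42.1% against 5.99% of cells (4.04) and GH3.1 in 57.9% against 9.15% of cells (3.89). Quiescent centre and stem cell niche genes had a median of 2.72 (percentile 100), with 3 of 7 measured members higher in all 3 flow cells. S phase genes had a median of 1.34 (11 of 23 higher, percentile 100), ribosomal protein genes 1.57 (70 of 88 higher, percentile 100, flow cell medians 1.45 to 1.67) and lateral root initiation regulators 0.82 (8 of 26 higher, percentile 99.9). HB53 was detected in 31.6% against 8.80% of cells, at 23.9 CPM (21.0 to 27.0) against 4.46 CPM (4.05 to 4.90) (log2 2.12, higher in 2 of 3 flow cells), with 1 cell giving 50.8% of its reads. PUCHI stood at -1.12, and at 0.76 among cells with at least 1000 genes. Protoplasting and stress response genes had a median of -1.79 (13 of 15 lower, percentile 0.230) and pericycle genes -5.21 (4 of 6 lower, percentile 0). A cell held a mean of 7.39 detected stress genes in the cluster and 7.40 elsewhere. Pooled values differ from flow cell medians for initiation regulators (0.23 to 0.41) and pericycle genes (-3.31 to -3.23), and with every cell weighed equally the initiation median was 0.27. The pericycle median was -4.59 without the second flow cell and -3.19 with another gene subset. PHO1 stood at -5.38, the auxin importer LAX3 (AT1G77690) at -3.88, the sucrose transporter SUC2 (AT1G22710) at -4.44, BAP1 at -4.40 and KNOLLE at -5.97, and GH3.6 (AT5G54510) had 3 against 8887 reads.

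The largest higher values outside the lists in cluster 6 were AT4G09940 at 7.25, the lipid transfer protein genes LTP3 at 6.61 and AT5G01870 at 5.67, the nucleolar NOP56-like gene AT3G12860 at 6.20, AT3G62630 at 5.31 (47.4% against 4.93% of cells), AT5G67390 at 5.28, FRS9 (AT4G38170) at 5.27 and AT1G15330 at 4.82. A single cell gave 70.1% of the AT3G12860 reads and 86.0% of the FRS9 reads. AT5G16250, RBCS1A, NAC020, AT4G26120 and MDHAR (AT3G09940) had 1 read each in the cluster, against 4616 to 10631 elsewhere, and NPF7.3 had 3 against 6818. Cells of cluster 6 had a median of 6730 detected genes, against 3814 in the other cells, and 15.4% of all measured genes were higher and 25.2% lower in all 3 flow cells. The overlap over other gene subsets was 0.604 (0.341 to 0.721), and the stem cell niche (0.96 to 3.32), S phase (1.13 to 1.90) and ribosomal (1.07 to 1.84) medians stayed above 0 in all 20 subsets. The stress median (-2.15 to 0.47) was above 0 in 2 of 20, and 0.42 with the ribosomal list not held out. Without the second flow cell the stem cell niche median was 0.63, and without the first it was 4.04 and the initiation median 0.45.

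Cluster 7 (13 cells) was marked by genes of mitosis. G2 and M phase genes had a median log2 fold of 5.10 (percentile 100), with 16 of 28 measured members higher in all 3 flow cells and flow cell medians of 3.1 to 5.94. CDC20.1, an activator of the anaphase-promoting complex, was detected in 84.6% against 2.91% of cells (log2 8.57), KNOLLE in 69.2% against 4.21% of cells (8.04), CYCB2;4 in 53.8% against 2.59% of cells (9.65) and ENODL15 in 84.6% against 3.88% of cells (6.27). CDC20.2 (AT4G33260), CYCB1;4, the spindle gene TPX2 (AT1G03780) and ENODL14 stood at 7.35, 7.13, 6.48 and 12.90. Outside the lists, AT5G16250 was detected in 84.6% against 1.94% of cells (9.56), and AT3G02640 and AT3G15550 stood at 9.05 and 8.79, while AT1G11220 had 1128 against 2 reads. S phase genes had a median of -3.03 (19 of 23 lower, percentile 0.050) and lateral root initiation regulators -2.43 (14 of 26 lower, percentile 0.270). The median share of cells with a read of a member was 15.4% against 16.2% for S phase genes. For initiation regulators it was 11.5% against 11.7%. The low medians of these 2 lists therefore rest on pooled reads more than on how many cells held a read. The helicase gene MCM7 (AT4G02060) and the auxin-conjugating enzyme gene GH3.5 (AT4G27260) had no read, at least 92.5-fold and 178-fold lower, and WRKY53 (AT4G23810) had 2 against 3035 reads. DIN10 (AT5G20250) and AT5G13950 had 1 read each, and ZF14 (AT1G58340), AT3G22600, PBP1 and RBCS1A none.

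With 13 cells, single cells weighed heavily in cluster 7, giving 87.8% of the AT1G11220 reads, 78.1% of the ENODL14 reads and 37.4% of the CDC20.1 reads, and the median of all measured genes was -0.64, with 7.55% of them higher and 29.1% lower in all 3 flow cells. The G2 and M phase median stayed above 0 in all 20 other gene subsets (2.92 to 5.73; overlap 0.532 (0.147 to 0.846)), whereas the S phase median was above 0 in 4 of 20 and the initiation median was 0.017 with another gene subset. Without the first flow cell the G2 and M phase median was 5.94 and the S phase median -2.25, without the second the initiation median -1.79 and without the third flow cell the S phase median -3.87. CDC20.1 and CDC20.2 are similar neighbouring copies, and the assignment of reads between them is uncertain.

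Cells were also ranked within each flow cell by the share of their reads in S, G2 and M phase genes, to ask what else differed between cells with high and low levels of division genes. The upper and the lower 1 in 3 held 107 cells each, with median shares of 1844 and 19.0 CPM, and the upper class took in 26 of 38 cells of cluster 6 and 12 of 13 of cluster 7, but 4 of 43 of cluster 5. The lower class held 2, 0 and 19 cells of these clusters, so the classes differ in their make-up of clusters. Ribosomal protein genes had a median log2 fold of 1.32 between the classes, with 72 of 88 higher in all 3 flow cells (percentile 100). Lateral root initiation regulators had a median of 1.16 (percentile 99.9), with 12 of 26 higher. HB53 was detected in 18.7% against 4.67% of cells, at 11.0 CPM (9.92 to 12.1) against 1.41 CPM (1.05 to 1.86) (log2 2.74), and PUCHI in 14.0% against 3.74% of cells, at 29.2 CPM (27.5 to 31.0) against 2.93 CPM (2.40 to 3.56) (3.09). Both genes were higher in all 3 flow cells, whereas LBD16 stood at 0.081 and CYCB1;1, which helped define the classes, at 1.96. CRF2, a cytokinin response factor, stood at 3.91, with 1 cell giving 79.8% of its reads. GH3.1, WOX5, the vascular regulator LHW (AT2G27230), PHV and HSFA2 stood at 2.85, 2.07, 2.33, 1.81 and 1.88.

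Lower in the upper class were pericycle genes, with a median of -2.12 (2 of 6 lower in all 3 flow cells, percentile 0.0300), cytokinin response genes at -1.15 (5 of 14, percentile 0.290), protoplasting and stress response genes at -0.86 (7 of 14, percentile 0.670) and green tissue genes at -2.05 (4 of 5, percentile 0.110). PHO1, ARR5, MYB36 (AT5G57620), GAPA, PSBO1 and RBCS1A stood at -2.22, -1.99, -2.43, -3.49, -2.05 and -8.10. The largest lower genes outside the lists were the protease gene AT4G11320 at -10.22, AT5G48110 at -6.74 and AT1G22330 at -6.66, and SBT4.12 (AT5G59090) had 2 against 1938 reads. The DNA repair gene BARD1 (AT1G04020) had no read in the lower class and was at least 866-fold higher in the upper, RACK1C_AT (AT3G18130), a receptor for activated C kinase gene, at least 682-fold, and AT3G02640, AT5G17160 and AT4G02800 at least 589 to 724-fold. AT5G16250 had 10534 against 1 reads, AT5G06590 1485 against 1 and AT2G23530 1533 against 2.

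The cycling classes are ranges of a score, and 43 cells lay within 25% of the score that bounds the upper class. The upper class had a median of 4741 detected genes, against 3666 in the lower, and 20.3% of all measured genes were higher and 16.0% lower in all 3 flow cells. HB53 was found in 3.74% of the 1 in 3 cells with fewest detected genes and in 20.4% of those with most. Classes were matched on gene number for ribosomal protein genes only. How far HB53, PUCHI and initiation regulators differ between classes with equal gene number is therefore not known. The cytokinin median was 1.37 with no filter on cells and -0.26 and -0.48 without the second and the third flow cell. The initiation median was 0.59 and 0.54 without the first and the third flow cell, and the stress median -0.51 without the second. With classes from the S phase share alone, CRF2 stood at -2.36 and AT5G16250 at -1.39, and with no filter on cells MYB36 stood at 4.65.

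**Figure D4:**
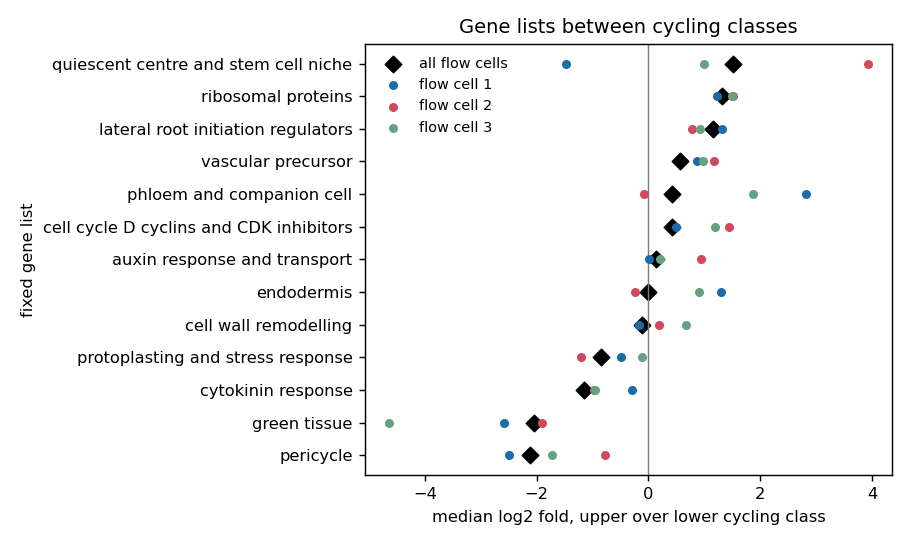
Diamonds give the median log2 fold of each fixed list between the upper and lower cycling class over all cells, and circles the median within each flow cell. Ribosomal protein genes (1.32) and lateral root initiation regulators (1.16) lie above 0 and pericycle genes (-2.12) below 0 on each flow cell, while the stem cell niche list differs in sign between flow cells.

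Gene lists were last compared across cells, as Spearman correlations of list shares within each flow cell after thinning, for 45 pairs of lists. S phase genes went together with G2 and M phase genes (rho 0.25 to 0.37 across flow cells) and with stem cell niche genes (0.11 to 0.28). They ran against pericycle genes (-0.23 to -0.10) and against the protoplasting and stress response list (-0.30 to -0.10). The stress list also ran against G2 and M phase genes (-0.17 to -0.13) and against stem cell niche genes (-0.23 to -0.085), and with pericycle genes (0.051 to 0.29). Lateral root initiation regulators correlated with G2 and M phase genes at 0.067 to 0.21 and with vascular precursor genes at 0.044 to 0.22. Of the 45 pairs, 27 changed sign between flow cells, and random directions would also leave some pairs with 1 sign. The pairs named here are not all of those that kept 1 sign. Among the others, auxin genes ran against stem cell niche genes (-0.24 to -0.020) and with vascular precursor genes (0.045 to 0.21). G2 and M phase genes went with endodermis genes (0.068 to 0.21). These are correlations among cells of 1 sample, which are not replicates, so no p-value is given, and shares of 1 total tend to run against each other.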

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

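The tests of other tissues, of green tissue in cluster 3 and of plates were chosen only after the results were seen. The 251 wells with fewer than 500 detected genes entered no comparison and had a median of 3922 reads and 52 detected genes. They stand out because their reads of primordium and stress genes were not 0. LBD16 had reads in 1 of these wells and JAZ1 in 14, a share of 5.58% (3.08 to 9.18) against 93.2% of cells. HB53 had no read in them, with an exact upper bound of 1.46% of wells.

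HB53 transcripts were counted in 11.5% of cells that had been sorted on a reporter under its promoter. The number of genes captured stays open as an explanation. HB53 was found in 20.4% (13.2 to 29.2) of the 1 in 3 cells with most detected genes. In the 1 in 3 with fewest the share was 3.74% (1.03 to 9.30). Gene number is itself a count of detected genes, so most sparse genes would be found more often where it is high. Gene number also differed between clusters, so this comparison cannot tell capture from expression. Read depth stays open, with 15.7% (9.45 to 24.0) in the deepest and 9.35% (4.57 to 16.5) in the shallowest 1 in 3. The condition written against it beforehand, a share in the deepest cells at or below 16.5%, was met, but the interval of that share reaches past it, and this stricter reading was chosen after the value was seen. Cells of other tissues stay open as well: 23.2% (18.4 to 28.5) of the 285 cells without HB53 held 2 or more markers of the endodermis, cortex, epidermis, root cap, xylem or green tissue, against 40.5% (24.8 to 57.9) of the cells with HB53. This is opposite to the direction that the explanation calls for, but the intervals overlap. The markers were sparse, with list medians of 0.466 to 8.07% of cells per gene. HB53 was also found more often where more genes were detected, which can raise marker counts, so this comparison cannot decide. The design holds 1 group, so no biological explanation was tested, among them a reporter protein that outlasts the transcript.

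Cluster 3 joined a median organelle share of 8.38% with a median of 1967 detected genes. Cells of green tissue were not shown to form the bulk of the cluster. Of its cells, 5.88% (1.23 to 16.2) held 2 or more green tissue markers, against 11.1% (7.59 to 15.4) outside it. A single cell gave 83.0% of its RBCS1A reads. The condition set against green tissue was met, but it was written after the results were seen. Fewer detected genes (median 1967, against 4456 in the other cells) also lower the share with markers, so this share cannot decide. Poor capture of nuclear transcripts stays open. Outside the cluster, organelle share and gene number had a median Spearman rho of -0.155 over flow cells (-0.159 to -0.129). This is weaker than the explanation needs and stronger than would exclude it. Cells of cluster 3 had a median of 121176 reads, against 277289 in the other cells. Wells below the cell filter had a median organelle share of 37.3%, against 2.42% in cells. Both contrasts go with poor capture, though no condition was set for them. No biological explanation was tested.

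Ribosomal protein genes had a median log2 fold of 1.32 in the upper against the lower cycling class. A plate batch is argued against, since the median was above 0 in 6 of 6 plates (0.71 to 2.32). A difference in the number of detected genes stays open as a part of it: with classes matched on gene number, at medians of 4116 and 4013 genes, the value was 1.11, below the bound of 1.16 set for excluding it and above 0. No biological explanation, such as a link between growth and division, was tested.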

How the results depend on the processing

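Some alternatives were chosen after seeing the data. These left out a flow cell, weighed each cell equally or dropped cluster 3 or cluster 7 from the reference. Others among them left organelle and 18S rRNA reads out of totals or used a narrower ribosomal list. The mean of the other clusters was the planned reference and was kept as an alternative, without a model. Moved means by more than 1 SD over flow cells, or outside the exact interval for a share. Of 678 list medians under alternatives, 538 moved by less, 118 moved by more in the same direction and 22 changed sign; for single genes the numbers were 2560, 615 and 95 of 3270. All 24 shares of cells with HB53, LBD16, PUCHI or CYCB1;1 stayed within their intervals, and 14 of 15 correlations stayed within their spread. Cluster shares were set against their intervals only for cells with at least 1000 genes, where 5 of 7 stayed within them. Cluster sizes also changed in other settings. The best match of cluster 7 (13 cells) held 38 cells with another random subset of the genes. The best match of cluster 1 (64 cells) held 21 cells without removal of the flow cell mean. The cause of the changes below was not tested, except that a changed clustering or cell filter also changes which cells are compared, matched to the main clusters by overlap. With no filter on cells, clusters 1 and 2 had 1 match of 154 wells in common, and clusters 4, 6 and 7 1 match of 103. At resolution 0.5, clusters 3 and 6 had 1 match of 58 cells in common. Values of these clusters in these settings are those of the merged cells, and a change of sign from a shared match is counted once for each cluster. No paired analysis was run because the sources used here tie no well to a replicate. For the same reason the replicate block, DESeq2, edgeR without composition factors, camera, fry and leaving out replicates were not run, and count splitting was not run because the counts are reads, not molecules. For shares of cells, what depth limits was examined by thinning to 115851 reads, where HB53 was detected in 10.1% of the 257 cells left, against 11.5% of all cells. Values below are log2, and genes without reads stand at the floor.

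With no filter on cells, these values changed sign. In the cycling classes cytokinin genes stood at 1.37, AT4G11320 at 2.33 and MYB36 at 4.65. In cluster 1 AT2G15780 stood at 7.24. In cluster 2 AT5G52390 stood at -0.090 and RBCS1A at 5.76. In cluster 3 green tissue genes stood at -2.68, AT2G16730 at -0.17, AT4G25090 at -2.50, CA1 at -1.83, PnsL1 at -1.47, NHL8 at 0.017, RBCS1A at -2.68 and CAB1 at -2.27. In cluster 4 G2/M genes stood at 2.57, PBP1 at -3.35, AT2G18150 at -2.63, NAI2 at -1.45, AT2G38380 at -0.18, ENODL14 at 4.23, AT5G16250 at 6.17, ENODL15 at 3.48, ACL5 at 1.50, CDC20.1 at 6.07 and KNOLLE at 5.00. In cluster 5 AGP14 stood at -5.34. In cluster 6 G2/M genes stood at 2.57, AT5G16250 at 6.17, KNOLLE at 5.00 and PUCHI at 1.75. In cluster 7 S phase genes stood at 1.25, initiation regulators at 0.84, AT5G13950 at 0.058, GH3.5 at 0.67 and MCM7 at 2.23. With another random subset of the genes, these values changed sign. In cluster 1 BRX stood at -0.37, AT1G26650 at -1.65, PEAR2 at -1.74 and BAP1 at -0.72. In cluster 2 RBCS1A stood at 5.27. In cluster 3 green tissue genes stood at -0.73, AT2G16730 at -3.12, CA1 at -2.02, DGD1 at 0.47, RBCS1A at -0.81, CAB1 at -1.68 and WOX11 at 1.02. In cluster 7 S phase genes stood at 0.13 and initiation regulators at 0.017. With at least 1000 genes per cell, these values changed sign. In cluster 1 stress genes stood at -0.091 and BAP1 at -0.53. In cluster 3 AT2G16730 stood at -2.75 and AT2G47670 at -1.32. In cluster 4 AT2G18150 stood at -0.27 and NAI2 at -0.032. In cluster 5 AGP14 stood at -1.86. In cluster 6 FRS9 stood at -0.10 and PUCHI at 0.76. Against the mean of the other clusters, these values changed sign. In cluster 1 G2/M genes stood at 0.0020 and KNOLLE at 1.37. In cluster 2 S phase genes stood at 1.00 and RBCS1A at 0.69. In cluster 6 G2/M genes stood at 0.20. With 3000 variable genes, these values changed sign. In cluster 1 stress genes stood at -0.54, vascular precursor genes at -0.0076 and BAP1 at -0.62. In cluster 3 AT2G16730 stood at -2.72 and AT2G47670 at -1.28. In cluster 4 SMC6A stood at -0.82 and KNOLLE at 0.059. In cluster 5 AGP14 stood at -4.59. In cluster 6 BAP1 stood at 0.47 and PUCHI at 0.53. At resolution 0.5, these values changed sign. In cluster 3 green tissue genes stood at -2.20, AT2G16730 at -3.93, CA1 at -2.68, PnsL1 at -3.22, LCB1 at 0.51, CSN5A at 0.54, ENODL15 at 0.14, RBCS1A at -2.20, CAB1 at -2.59 and WOX5 at 3.23. In cluster 6 PUCHI stood at 0.25. At resolution 1.2, these values changed sign. In cluster 1 stress genes stood at -0.20 and BAP1 at -0.20. In cluster 3 green tissue genes stood at -0.94, AT2G16730 at -2.27, CA1 at -1.16, PnsL1 at -2.0, RBCS1A at -0.55 and CAB1 at -0.94. Against other cells without cluster 7, these values changed sign. In cluster 1 G2/M genes stood at 0.17, ENODL14 at 1.42 and KNOLLE at 1.97. In cluster 2 ENODL14 stood at 0.74. In cluster 3 ENODL14 stood at 3.1. In cluster 5 ENODL14 stood at 1.38. With at most 10% organelle reads per cell, these values changed sign. In cluster 2 S phase genes stood at 0.022. In cluster 3 AT4G25090 stood at -3.44, AT2G28990 at -0.50, AT5G38310 at -0.35 and WOX11 at 0.21. In cluster 6 PUCHI stood at 0.50. Without removal of the flow cell mean, these values changed sign. In cluster 1 phloem genes stood at -0.51, CER1 at -5.11, PIP5K4 at -2.18, NAC020 at -0.37 and SMXL5 at -0.96. In cluster 3 AT2G16730 stood at -2.97. With classes from the S phase share, in the cycling classes AT5G16250 stood at -1.39, AT3G02640 at -3.33, AT2G23530 at -0.88, AT5G17160 at -3.69, AT4G02800 at -3.60 and CRF2 at -2.36 and changed sign.

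With no filter on cells, these values moved in the same direction. In the cycling classes green tissue genes stood at -3.47, stress genes at -0.18 and ribosomal genes at 0.93. In cluster 1 ribosomal genes stood at -1.06. In cluster 2 pericycle genes stood at -0.24. In cluster 3 G2/M genes stood at -2.60. In cluster 4 vascular precursor genes stood at -0.13. In cluster 5 ribosomal genes stood at -0.69. In cluster 6 pericycle genes stood at -2.19 and stress genes at -0.89. In cluster 7 G2/M genes stood at 2.57. With another random subset of the genes, these values moved in the same direction. In cluster 1 G2/M genes stood at -4.01, phloem genes at 0.48, stress genes at 0.11 and ribosomal genes at -0.95. In cluster 2 G2/M genes stood at -4.33, S phase genes at -2.20 and pericycle genes at -2.43. In cluster 5 S phase genes stood at -2.12. In cluster 6 G2/M genes stood at -0.72, initiation regulators at 0.65, pericycle genes at -3.19 and ribosomal genes at 1.74. With at least 1000 genes per cell, these values moved in the same direction. In cluster 2 S phase genes stood at -1.99 and pericycle genes at -2.09. In cluster 4 G2/M genes stood at -3.63. In cluster 5 G2/M genes stood at -5.27 and vascular precursor genes at -2.01. In cluster 6 initiation regulators stood at 0.43, pericycle genes at -3.12 and ribosomal genes at 1.81. The share of cells in cluster 3 was 10.9%. The share of cells in cluster 5 was 6.07%. Against the mean of the other clusters, these values moved in the same direction. In cluster 2 pericycle genes stood at -1.81. In cluster 3 G2/M genes stood at -2.53. In cluster 4 G2/M genes stood at -0.59. In cluster 5 G2/M genes stood at -1.51, S phase genes at -2.35, pericycle genes at 4.00 and vascular precursor genes at -2.15. In cluster 6 S phase genes stood at 2.13, initiation regulators at 1.74 and pericycle genes at -3.49. In cluster 7 G2/M genes stood at 6.69 and initiation regulators at -1.09. With 3000 variable genes, these values moved in the same direction. In cluster 4 G2/M genes stood at -0.67. In cluster 6 G2/M genes stood at -0.92, initiation regulators at 0.61 and pericycle genes at -3.04. In cluster 7 S phase genes stood at -0.25 and initiation regulators at -0.22. At resolution 0.5, these values moved in the same direction. In cluster 3 G2/M genes stood at -2.24. In cluster 6 initiation regulators stood at 0.29, pericycle genes at -2.22 and ribosomal genes at 1.42. At resolution 1.2, these values moved in the same direction. In cluster 2 pericycle genes stood at -2.68. In cluster 4 vascular precursor genes stood at -3.92. In cluster 5 G2/M genes stood at -5.47, ribosomal genes at -0.96 and vascular precursor genes at -2.21. In cluster 6 pericycle genes stood at -5.28. Against other cells without cluster 7, these values moved in the same direction. In cluster 2 G2/M genes stood at -1.34. In cluster 3 G2/M genes stood at -3.02. In cluster 4 G2/M genes stood at -0.60. In cluster 5 G2/M genes stood at -1.43. In cluster 6 G2/M genes stood at -0.0069, initiation regulators at 0.96 and pericycle genes at -5.30. With at most 10% organelle reads per cell, these values moved in the same direction. In cluster 5 S phase genes stood at -3.25 and vascular precursor genes at -3.82. In cluster 6 G2/M genes stood at -1.05, initiation regulators at 0.54 and pericycle genes at -3.61. Without removal of the flow cell mean, these values moved in the same direction. In cluster 1 stress genes stood at 2.36 and ribosomal genes at -0.18. In cluster 6 pericycle genes stood at -5.28. In cluster 7 S phase genes stood at -0.61 and initiation regulators at -0.44. With every cell weighed equally, these values moved in the same direction. In the cycling classes cytokinin genes stood at -0.38, green tissue genes at -4.13, initiation regulators at 0.83 and ribosomal genes at 1.53. In cluster 2 pericycle genes stood at -2.27. In cluster 5 ribosomal genes stood at -1.39. In cluster 6 initiation regulators stood at 0.27 and pericycle genes at -4.69. In cluster 7 S phase genes stood at -1.21. With classes from the S phase share, in the cycling classes initiation regulators stood at 0.73 and moved in the same direction. With library size only, these values moved in the same direction. In the cycling classes ribosomal genes stood at 1.54. In cluster 2 ribosomal genes stood at -1.25. In cluster 6 initiation regulators stood at 1.12, pericycle genes at -4.91 and ribosomal genes at 1.87. With classes from the G2/M share, in the cycling classes stress genes stood at -0.19 and ribosomal genes at 0.92 and moved in the same direction. With the upper against the lower 0.5 of cells, in the cycling classes initiation regulators stood at 0.58 and ribosomal genes at 1.07 and moved in the same direction. With no filter on low counts, in cluster 6 pericycle genes stood at -5.05 and moved in the same direction. Against other cells without cluster 3, in cluster 6 pericycle genes stood at -5.33 and moved in the same direction. With the score taken after thinning, in the cycling classes initiation regulators stood at 0.81 and moved in the same direction. With cells thinned to the median of totals, the rho of pericycle and stress genes moved to 0.042.

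Leaving out 1 flow cell at a time gave these ranges where a value moved. The cycling classes had cytokinin genes -1.01 to -0.26 and initiation regulators 0.54 to 1.41. Cluster 2 had G2/M genes -4.67 to -3.06 and S phase genes -1.17 to 0.058. Cluster 3 had G2/M genes -5.05 to -3.18 and green tissue genes 0.60 to 4.91. Cluster 4 had G2/M genes -3.32 to -2.58 and vascular precursor genes -3.63 to -1.99. Cluster 5 had S phase genes -3.30 to -2.60 and vascular precursor genes -4.27 to -2.41. Cluster 6 had initiation regulators 0.45 to 0.96, pericycle genes -4.88 to -4.59 and stem cell niche genes 0.63 to 4.04.

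With 20 other random gene subsets, 11 gave 7 clusters. Over all settings with new clusters, the best overlap ranged from 0.126 (cluster 7) upwards, so a changed value may reflect other cells rather than other levels, as for the cluster 7 S phase median, -3.74 to 1.07 over the subsets and 0.13 with the planned one.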

Other observations

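The comparisons and genes here were chosen after the data had been examined. The 39 cells with reads of WOX5 were compared with the 283 cells without for genes picked by hand, not for a fixed list. The stem cell gene BBM was detected in 43.6% (27.8 to 60.4) against 6.01% (3.54 to 9.44) of them, WOX7 in 43.6% (27.8 to 60.4) against 5.65% (3.27 to 9.02), GH3.1 in 48.7% (32.4 to 65.2) against 10.2% (6.97 to 14.4) and PLT3 in 69.2% (52.4 to 83.0) against 43.5% (37.6 to 49.5). The differences of these genes had the same direction on all 3 flow cells. HB53 was detected in 25.6% (13 to 42.1) against 9.54% (6.38 to 13.6), also with the same direction on each flow cell, and LBD16 in 43.6% (27.8 to 60.4) against 35.0% (29.4 to 40.9), with the opposite direction on 1 flow cell. MYB56 (AT5G17800) was less frequent in the cells with WOX5, in 2.56% (0.0649 to 13.5) against 12% (8.47 to 16.4), on all 3 flow cells, whereas for PUCHI, in 5.13% (0.627 to 17.3) against 9.54% (6.38 to 13.6), the direction differed between flow cells. Cells with WOX5 reads were not matched on gene number, and cluster 6, of whose cells 57.9% had WOX5 reads, had the highest median gene number of the 7 clusters.

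Further genes kept out of the clustering were detected more often in 1 cluster than in the other cells. In cluster 2 these were the leucine zipper protein gene ZPR1 in 58.1% against 5.77% of cells, the AP2/ERF gene Rap2.6L (AT5G13330) in 56.5% against 10.8% of cells and MYB63 (AT1G79180) in 37.1% against 13.8% of cells. Cluster 5 had the GRAS family gene AT2G29060 in 46.5% against 3.58% of cells and the ascorbate recycling gene MDHAR in 44.2% against 3.58% of cells. Cluster 6 had the histone deacetylase-related gene HDT4 in 55.3% against 4.93% of cells and the gibberellin-regulated gene AT5G14920 in 55.3% against 4.58% of cells. In cluster 4, where more genes were detected per cell, the actin-nucleating formin gene FH4 (AT1G24150) in 39.2% against 14.8% of cells was of this kind.

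Heat shock genes (55 by product name, some of them used to build the clusters) had a median of 3381 CPM per cell, 2680.2 to 3954 across plates, and a percentile 90 of 6422 to 20411 CPM across plates. In cluster 1 the median was 4518 CPM and the percentile 90 was 33109.6 CPM, against a percentile 90 of 12260.1 CPM over all cells, and the medians of clusters 6 and 7 were 4346 and 4057 CPM. The most abundant transcripts were the 18S rRNA gene AT3G41768, with 4.44% of reads, and the mitochondrial gene ATMG00020, with 2.02%. They were followed by UBQ10 (AT4G05320) at 0.608%, NADP-ME2 (AT5G11670) at 0.573%, the oxylipin reductase gene OPR1 (AT1G76680) at 0.570% and AT5G35735 at 0.565%. Next came the dehydrin genes ERD10 (AT1G20450) at 0.559% and COR47 (AT1G20440) at 0.463%, and the glutathione transferase gene GSTF8 (AT2G47730) at 0.462%.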
